A study of Mus musculus with 2 samples.

How the data were processed

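Genomic DNA of sorted mouse spermatogonial stem cells was sequenced by the submitters in 2 libraries, 1 from cells with a mutant Tex11 allele and 1 from a corrected line (label HDR-1), both at passage 14. Per the submitters' processing notes, the tools were fastp, BWA and GATK and the genome was mm10; versions and settings are not given in the sources used here.

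The values came from 1 table of called sites. Per the file headers and its caller statistics, the authors called sites in 1 library against the other as matched control, kept sites that passed the caller's filters and annotated them with RefSeq genes. The deposited allele share of a call is a fraction from 0 to 1, per the file headers the maximum score. The deposited depth is a count of reads in the shallower library, and a further count by the authors gives the alternative reads. The authors' deposited table also marks 3 thresholds: the share mark and the depth mark followed the deposited columns at all 5812 calls (over 0.35 and over 10), whereas the mark for more than 10 alternative reads followed its column at 5579. The other 233 calls were marked with 10 or fewer reads; none of these passed the other thresholds jointly, so 43 calls passed all 3 marks by either reading.

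The table's 14 per-library columns carry names that match neither sample's labels and were not used in any step. The cell line that carries an allele, and the direction of each difference, are therefore unknown here. A further 17 lines of the table were not analysed here. The total depth of each library was also not analysed; the depth at called sites stands in for it.

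Calls were sorted into single-base changes, changes of several bases, deletions and insertions from the deposited alleles, and single-base changes were folded over both strands into 6 classes. Mapping quality, base quality and insert length are the caller's medians over reference and alternative reads at a site. A call counted as protein-changing if annotated as nonsynonymous, stop, frameshift, in-frame or splice-site, except 1 substitution that kept its residue. Gene coordinates came from a RefSeq gene table of GRCm38.p6, the mm10 assembly; of 1190 gene names with a call, 1183 matched it. Chromosome lengths were not used here, and the end of the last gene stood in for them.

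Shares were given with 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only. Groups of calls were compared by two-sided Fisher's exact tests or chi-square tests and medians by permutation tests with 100000 resamples, or by an exact permutation test where a group had fewer than 10 calls. Sites are not replicates, so p-values describe these libraries and not the conditions. Calls in clusters are not independent, so p-values of tests that include them may be too small even for these libraries. Gene lists of spermatogonial stem cell, meiosis, DNA repair and cancer driver genes, and a list of multigene families, were fixed before the data were examined. Predicted genes of the Gm series were counted as a family only where a digit follows, narrower than first written. List tests were adjusted by Benjamini-Hochberg over the 4 lists.

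The rule for named genes, fixed before the data were examined, took up to 30 genes: list genes with a protein-changing call, genes with a stop, frameshift or splice-site call, then genes with the most protein-changing calls with ties by depth, multigene families only among the top 5, and every call inside Tex11. Genes named outside it were chosen after their values were seen. The call of 1 list gene is counted but not reported here by name.

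Some tests fixed beforehand needed reads or genotypes per library and were not run: Fisher's exact test of allele reads per site, private sites in each direction and heterozygous calls per library. In place of the last, the percent of X and Y calls with a share of 0.5 or less was used. Alternatives varied depth, clustering, families, chromosomes, quality (the caller's log odds), annotation and windows. Alternatives chosen after seeing the data included full mapping quality (60), no tandem repeats, a share of at least 0.3, length-matched genes and X against autosomes at like depth. Where the first plan set a depth limit for either library, the summed depth was used.

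The steps were tested on simulated data. Of 5783 simulated calls at uniform positions, 0.623% lay within 1 kb of another, and 30.3% after 30.0% had been placed in pairs. All of 4000 simulated transitions and transversions were sorted correctly. Shuffled bases of the 68 long deletions read as intron ends in 2.99% of cases, and planted ends were found in 100%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.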

Results

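Whole-genome sequencing compared spermatogonial stem cells (the stem cells of the male germ line, grown in culture) carrying a mutant allele of the X-linked meiosis gene Tex11 (labelled Tex11PM) with a corrected line labelled HDR-1. Each of the 2 cell lines, both at passage 14, was sequenced as 1 library. The design asks which sequence differences separate the corrected line from its parent. The authors' deposited table lists sites called in 1 library against the other as control, and 5812 of its calls were analysed. Its per-library columns were not used, so the values do not say which cell line carries an allele. There were no replicates, and intervals cover counting error only. In the authors' deposited table the shallower library had a median of 20 reads at a call (quartiles 14 and 31), and the libraries together a median of 53 reads.

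At Tex11, the gene named by the labels (X, 100838648 to 101059639, mm10), 1 call was analysed. It was an intronic T-to-A change at X position 100916936, with an allele share of 0.125, 3 alternative reads and 22 reads in the shallower library. The alternative reads at this Tex11 site had a median mapping quality of 37. No exonic call of Tex11 was among those analysed, and 17 further lines of the table were not analysed here, so the corrected base itself could not be examined. Within 1 Mb of Tex11 there were 8 calls, none of which passed all 3 of the authors' thresholds. They comprised 2 intronic calls in Eda, a ligand gene of skin appendage development, 3 synonymous calls in Nlgn3, a synaptic adhesion gene, 2 intronic calls in Nhsl2 and the call in Tex11. Their highest allele share was 0.235, at Nlgn3.

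Most calls had few supporting reads. The alternative allele share had a median of 0.165 over the 5812 calls, and 79.7% of calls (95% exact binomial interval 78.6 to 80.7) rested on 4 or fewer alternative reads. The authors' thresholds were an allele share over 0.35, a depth over 10 and more than 10 alternative reads. The first was passed by 348 calls and the second by 5155. More than 10 alternative reads were listed for 66 calls, although the table marks 299 as past that threshold. All 3 were passed by 43 calls (0.740%, interval 0.536 to 0.995). The plot of allele shares sets these 43 beside the rest.

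**Figure D1:**
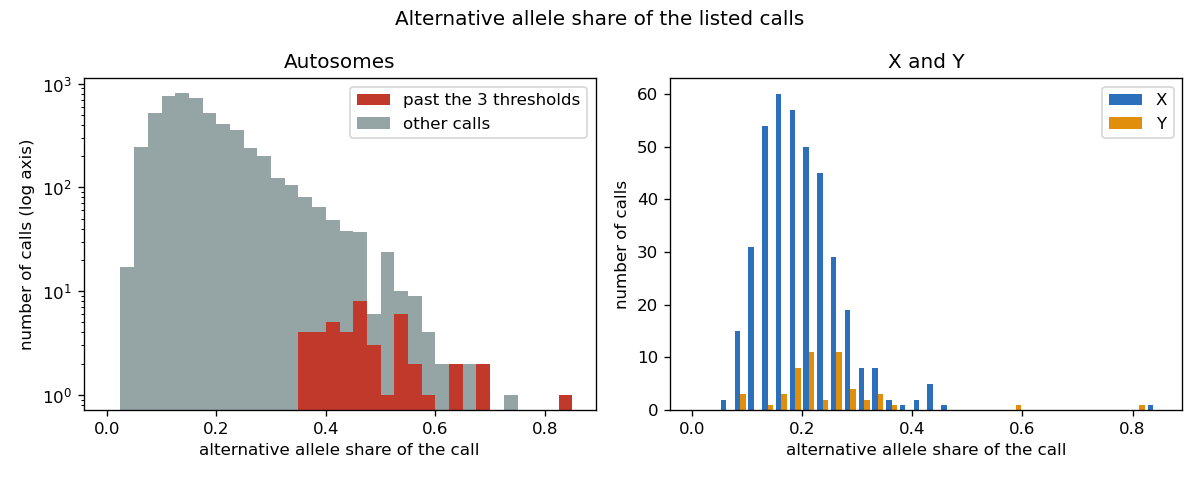
Number of calls by alternative allele share, in bins of the share, on autosomes (left, log axis, calls past the 3 thresholds stacked below the others) and on X and Y (right, linear axis). The autosomal median was 0.161, and the 43 calls past the thresholds had a median of 0.461.

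The 43 calls past the thresholds included a stop codon in Dgkq, which encodes a diacylglycerol kinase. This call (5, position 108650299, exon 18, protein change E463X) had an allele share of 0.354, 12 alternative reads and 32 reads in the shallower library. It was the only exonic call of the 43. The others were 25 intergenic calls, 1 intronic call in a noncoding gene and 16 intronic calls in 16 genes. Among the intronic calls, which were chosen for naming after their values were seen, Cdk14, a cyclin-dependent kinase gene, had a share of 0.691 (17 alternative reads). Nrxn3, a synaptic adhesion gene, had 0.636 (26 alternative reads) and Spop, a ubiquitin ligase adaptor gene, had 0.567 (23 alternative reads). Gldc, of the glycine cleavage system, had 0.476 (23 alternative reads) and Nos1, a nitric oxide synthase gene, had 0.481 (15 alternative reads). Of the 43 calls, 9.30% lay within 1 kb of another call, against 43.4% of the other calls (two-sided Fisher's exact test, p = 1.51e-06). Full mapping quality of the alternative reads was found in 90.7% of the 43 and in 42.0% of the others (two-sided Fisher's exact test, p = 3.52e-11). None of the 43 lay on X or Y, which held 7.59% of all calls. No call there had more than 10 alternative reads listed, so none could pass by the listed reads. By the table's marks, 7 of 390 X calls were past both the depth and the alternative-read threshold, but none of these was among the 43.

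Protein-changing calls numbered 50 in 38 genes. A stop codon, frameshift or splice-site change was listed in 15 of these genes, in 17 calls. Apart from Dgkq, no protein-changing call passed the 3 thresholds, and the highest allele share among them was 0.297, in Muc4. Frameshift deletions were listed in Arrb2, a beta-arrestin gene, Rrm2, a ribonucleotide reductase subunit gene, Gramd1a and the X-linked filamin gene Flna. Splice-site deletions were listed in Ptprc, which encodes the leukocyte phosphatase CD45, in the T-cell adaptor gene Lat (2 calls), in the kinase gene Mknk2 and in the glycolytic gene Tpi1. Splice-site insertions were listed in Vim (vimentin, 67 bases), Serinc3 (31 bases), Lgals1 (galectin 1, 74 bases) and Hprt, of purine salvage (23 bases). They rested on 2 to 4 alternative reads, at allele shares of 0.058 to 0.093. Lgals1 also had a frameshift insertion beside the splice-site call. Both Lgals1 calls had 3 alternative reads, with a median insert of 1302 bases. Single-base splice-site changes were listed in Arhgdib and Tango6.

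The deletions in Arrb2, Rrm2, Gramd1a, Flna, Ptprc, Lat, Mknk2 and Tpi1 shared a feature of sequence. Each of the 9 removed between 79 and 114 bases, and each could be read with the bases that end an intron (GT and AG, on either strand) at its ends, allowing a shift of up to 5 bases; the flanking bases that a shift needs were not checked. The same was true of 2 of the 59 other deletions of 50 bases or more outside tandem repeats (3.39%, interval 0.413 to 11.7; two-sided Fisher's exact test, p = 1.12e-09). Without a shift it held for 4 of the 9, in Mknk2, Tpi1 and Lat, and for 1 of the 59 (two-sided Fisher's exact test, p = 0.000725). The allele shares of the 9 ran from 0.050 in Rrm2 to 0.139 in Tpi1. Median insert lengths of the alternative reads were 65 bases in both Lat deletions, 79 in Mknk2, 95 in Flna and 135 in Tpi1, but 245 in Arrb2, 252 in Gramd1a, 261 in Ptprc and 273 in Rrm2. The other long deletions had a median of 256 bases. This length limit and this comparison were chosen after the calls were seen.

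**Figure D2:**
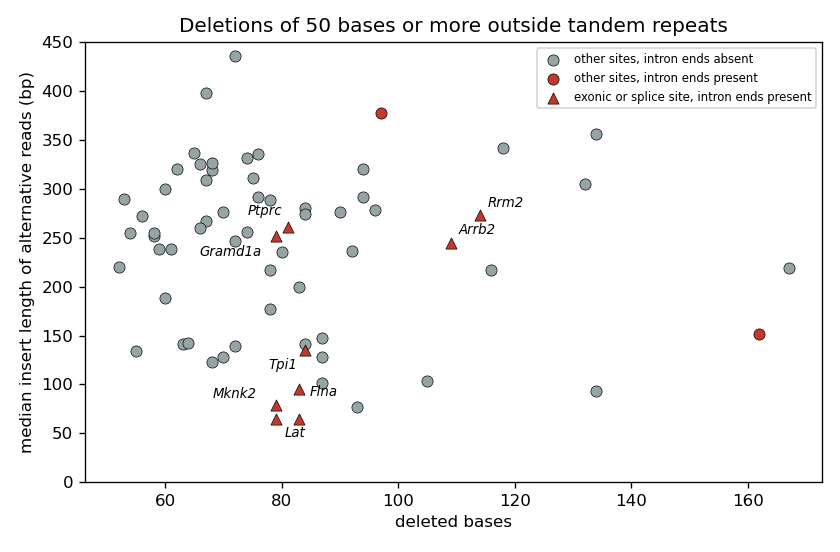
Deleted bases and median insert length of the alternative reads for the 68 deletions of 50 bases or more outside tandem repeats. Triangles are exonic or splice-site deletions, circles other sites, and red marks deletions that can be read with intron ends. The 9 triangles are all red, with insert lengths from 65 to 273 bases.

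The remaining 15 genes of the rule for named genes carried missense or in-frame changes. Muc4, a mucin gene with long coding repeats, had 4 such calls, at allele shares of 0.092 to 0.297. Aplp2, of the amyloid precursor family, had 3 within exon 4 (Q154K, N148K and D147E) at shares of 0.093 to 0.095, and the vomeronasal receptor gene Vmn2r89 had 3 within exon 3 at shares of 0.100 to 0.122. Cgn, which encodes the tight junction protein cingulin, and Trim43a had 2 calls each. C87977, Gon4l, A2ml1, Ifi203, Ifi206, Nlrp1b, Teddm1a, Plekha5, Tmcc2 and Cct2 had 1 call each, with shares from 0.064 in Nlrp1b to 0.294 in Gon4l. Of the 28 nonsynonymous calls, 23 had a median alternative mapping quality under 60, and 12 of the 50 protein-changing calls fell in multigene families whose reads can be shared between copies.

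None of the 4 gene lists fixed before the data were examined had a protein-changing call, where at most 0.108 genes were expected per list. Calls of any kind fell in 3 of 39 spermatogonial stem cell genes (Etv5, Taf4b and Adgra3), 7 of 57 meiosis genes, 5 of 62 DNA repair genes and 4 of 45 cancer driver genes. The meiosis genes were Tex11, Spo11, which makes the breaks that start meiotic recombination, Hsf2bp, Smc1b, Mei4, Hfm1 and Ythdc2. Their share of 12.3% compared with 4.95% of other protein-coding genes (odds ratio 2.69, two-sided Fisher's exact test, p = 0.0223, Benjamini-Hochberg adjusted p = 0.0892 over the 4 lists), so the difference did not pass the adjusted threshold. Against genes matched on length, 7 meiosis genes compared with a mean of 3.62 genes in 10000 draws, 95% of which lay between 1 and 7. The two-sided p from these draws was 0.130. The DNA repair genes included Brca1, Pms1, Xrcc1 and Fanca (odds ratio 1.68, adjusted p = 0.379) and the cancer driver genes Rb1, Apc, Pik3ca and Pik3r1 (odds ratio 1.87, adjusted p = 0.379), and the stem cell list had an odds ratio of 1.59 (adjusted p = 0.443), all by two-sided Fisher's exact test. None of the 23 calls in the 19 list genes passed all 3 thresholds, and their highest share was 0.304, in Pms1. Outside introns, the Etv5 call was synonymous and the Pik3ca call lay in the 3' untranslated region.

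Over the genome, 66.4% of calls were intergenic, 27.3% intronic in coding genes and 2.94% intronic in noncoding genes. Exonic calls made up 1.07% and splice-site calls 0.189%. Coding effects comprised 28 nonsynonymous and 22 synonymous changes, with the remainder as stops, frameshifts and in-frame changes.

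Calls were unevenly spread along the chromosomes, and genes of the fixed multigene families held 4.49% of them. The window with the most calls was 113 to 114 Mb of chromosome 4, with 62 calls around the gene Skint5. Skint5 and Skint6 held 42 and 25 calls in all. Snhg14, the long noncoding host transcript of an imprinted region on chromosome 7, held 40 calls. A window of chromosome 1 at 173 Mb with the interferon-inducible gene Ifi203 held 34 calls, a window of chromosome 7 at 41 Mb with vomeronasal receptor genes such as Vmn2r57 held 27, and a window of chromosome 6 at 130 Mb with natural killer receptor genes (Klra12, Klra15 and Klra22) held 23. The 22 windows of 1 Mb with 15 or more calls made up 0.805% of windows and held 9.04% of calls. Chromosome 7 had 3.23 calls per Mb and chromosome 4 had 3.18, while chromosome 2 had 1.44 and Y 0.561 (chi-square over autosomes against length, p = 3.69e-54, with calls in clusters not independent). Without calls within 1 kb of another, the counts still differed from length (chi-square, p = 2.59e-11), at 1.66 per Mb on chromosome 4 and 1.47 on chromosome 7.

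**Figure D3:**
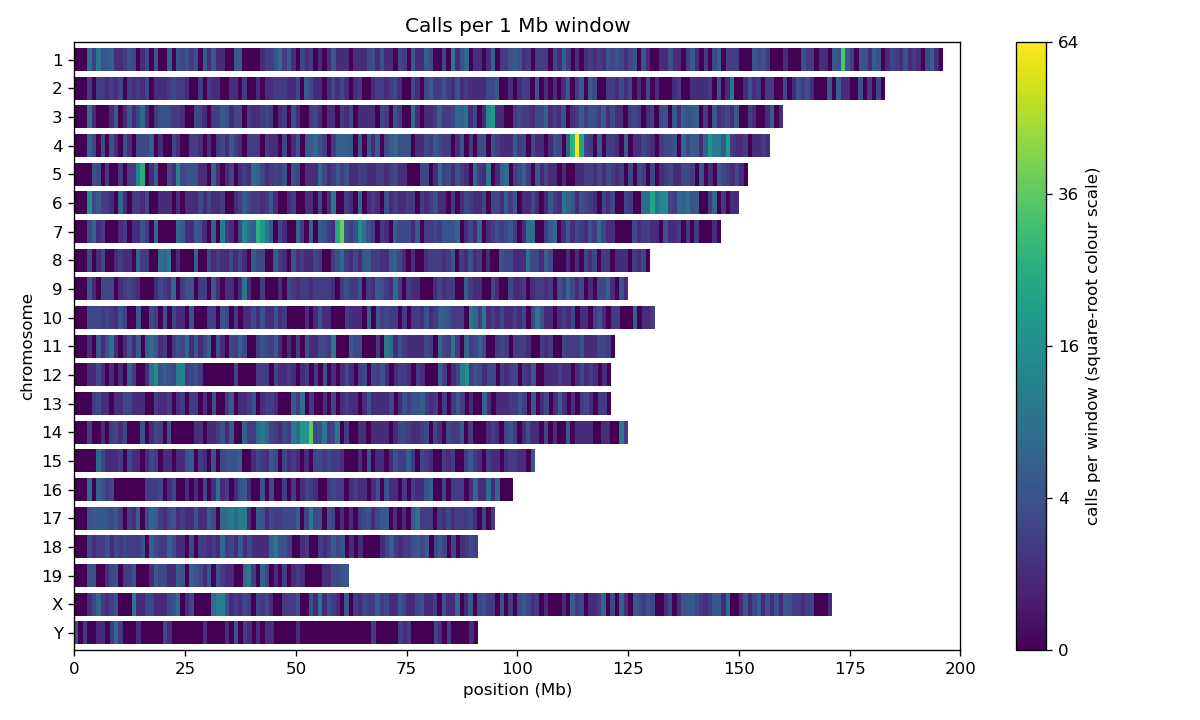
Calls per 1 Mb window along each chromosome, position in Mb, colour on a square-root scale. The window of chromosome 4 with Skint5 held 62 calls, and the window of chromosome 7 at 60 Mb with Snhg14 held 39.

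Of all calls, 43.2% (interval 41.9 to 44.5) lay within 1 kb of another. Single-base calls in such clusters had an alternative mapping quality under 60 in 83.6% of cases, against 59.6% of isolated ones (two-sided Fisher's exact test, p = 3.99e-63). Calls in clusters are not independent, so this p-value may be too small. Among calls with full mapping quality, 20.7% lay within 1 kb of another such call, with neighbours of lower mapping quality left out.

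Single-base changes numbered 3882, deletions 1337, insertions 301 and changes of several bases 292. C-to-T changes made up 31.9% of single-base calls (interval 30.4 to 33.4), T-to-C 22.5%, T-to-G 13.8%, T-to-A 12.3%, C-to-A 11.4% and C-to-G 8.14%, and transitions together 54.4%. With full mapping quality, T-to-G made up 28.1% against 8.32% elsewhere (two-sided Fisher's exact test, p = 2.89e-52), and transitions were 41.9% against 59.2% (two-sided Fisher's exact test, p = 3.87e-22). Among the 37 single-base calls past the 3 thresholds, T-to-G made up 10.8% (interval 3.03 to 25.4) and transitions 51.4% (interval 34.4 to 68.1), too few calls to tell their transition share from that of either group.

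**Figure D4:**
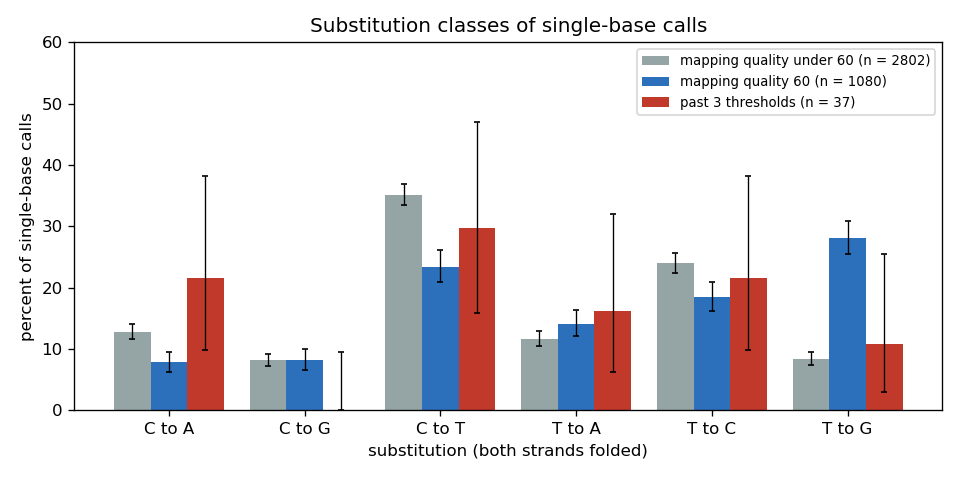
Percent of single-base calls in 6 substitution classes, with both strands folded. Bars are calls with alternative mapping quality under 60 (n = 2802), with 60 (n = 1080) and past the 3 thresholds (n = 37, also counted in the other bars), and whiskers are 95% exact binomial intervals. T-to-G was 28.1% with mapping quality 60 and 8.32% below it.

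Male cells carry a single copy each of X and Y. In sequence that occurs only once there, an allele present in every cell of 1 line would have a share near 1. Of the 441 calls on these chromosomes, 99.3% (interval 98.0 to 99.9) had a share of 0.5 or less. Only 61 of the X calls and none of the Y calls had full mapping quality, and all 61 had a share of 0.5 or less. For the other calls, a low share cannot tell a partial allele from reads of similar sequences. On X, 1 of 390 calls exceeded 0.5, between Gria3 and Thoc2, with a share of 0.833, 4 alternative reads and 4 reads in the shallower library. On Y, 2 of 51 exceeded it. The call beside Gm21679 had a share of 0.819 with 10 alternative reads and 9 reads in the shallower library, and the call between Orly and Sly a share of 0.6 with 2 alternative reads. The median share was 0.187 on X and 0.161 on autosomes (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples give), where the shallower library had medians of 15 and 21 reads. Among calls with 14 to 16 reads in the shallower library the order turned, with medians of 0.188 on X (n = 105) and 0.210 on autosomes (n = 609; permutation test, two-sided, p = 0.0239).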

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

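The alternatives with full mapping quality, without tandem repeats, with an allele share of at least 0.3, with genes matched on length, with X against autosomes at like depth, with inserts listed as 0 left out and with other deletion settings, and all those of the 43 calls and the named genes, were chosen after the results were seen; the rest were fixed before the data were examined.

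The count of 43 calls past the 3 thresholds lay between 38 and 43 under 7 filters; the filters on a share of at least 0.3 and on autosomes could not remove any of the 43. The count of 5812 calls became 3037 with at least 20 reads in both libraries, 3446 without calls within 100 bp of another, 2911 at or above the median quality, 2461 with full mapping quality and 613 with a share of at least 0.3. Transitions (54.4%) became 52.3%, 51.9%, 41.9% and 57.2% with at least 20 reads, without close calls, with full mapping quality and with a share of at least 0.3. Calls inside genes (32.3%) became 33.6% without close calls, 29.1% without multigene families, 33.6% on autosomes, 40.3% with full mapping quality, 31.1% without tandem repeats, 31.0% with a share of at least 0.3 and 41.8% by the spans of the gene table. Calls within 1 kb of another (43.2%) became 47.0% at or above the median quality, 20.7% with full mapping quality, 49.1% without tandem repeats, 30.8% with a share of at least 0.3 and 47.8% at a distance of 10 kb. Under each filter only neighbours among the calls left were counted. Calls on X and Y with a share of 0.5 or less were 100% with at least 20 reads (76 calls left on X and 4 on Y) and with full mapping quality (61 left on X and none on Y). Around Tex11, 8 calls became 20 within 5 Mb, 2 with full mapping quality and 0 with a share of at least 0.3. The 9 deletions with intron ends became 4 without a shift of the ends. With the Lat deletions counted once, the difference in median insert length from other long deletions was -66 bases (exact permutation test, two-sided, p = 0.0978) in place of -121 (p = 0.00929). With protein-changing calls only, the odds ratio of each of the 4 gene lists was 0 (two-sided Fisher's exact test, p = 1); only 38 of the other genes had such a call, with at most 0.108 genes expected per list, which says nothing of enrichment. The larger window and distance add calls by construction; the cause of the other changes was not tested.

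Of the 30 named genes, 29 had no protein-changing call left with a share of at least 0.3, 13 without close calls and 10 with full mapping quality. Few reads limit the precision of single shares, as 79.7% of calls rested on 4 or fewer alternative reads. Difference in share between libraries, absence of alternative reads in the other library, and the depth and threshold settings of the test per site were not run. Leaving out a library was not possible with 1 per cell line. No paired analysis was possible because each cell line had 1 library and the results came from no paired test.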

Other observations

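All tests in this part were chosen after the result was seen, except the comparison of base quality between T-to-G and other calls, which was written down before its result. No explanation tied to the correction of Tex11 was tested, since the values do not show which cell line carries an allele.

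Short tandem repeats held 954 of the 1638 insertions and deletions (58.2%, exact binomial interval 55.8 to 60.6), and 849 of these 954 were deletions (89.0%, interval 86.8 to 90.9). Units of AC or GT made up 49.0% of the repeat calls. The repeat calls had a median allele share of 0.197 and a median of 3 alternative reads. List genes with such deletions included Taf4b.

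Calls with short inserts were more often exonic or at a splice site than other calls. Of 65 calls whose alternative reads had a recorded median insert under 110 bases, 12 were exonic or at a splice site (18.5%), against 0.992% of 5643 calls with longer inserts (two-sided Fisher's exact test, p = 7.32e-12). The 104 calls with an insert listed as 0, among them those in Aplp2, were left out. The 12 (7 of them at splice sites) lay in 9 genes and included the 3 synonymous Nlgn3 calls near Tex11, with inserts of 101 bases. Splice-site calls in Arhgdib, Hprt, Serinc3 and Vim had inserts of 77 to 90 bases. The rest were the Lat, Mknk2 and Flna deletions (65 to 95 bases) and a Cct2 insertion (79 bases). Those deletions are also treated in the next paragraph, so these observations are not independent of each other.

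The long deletions in Ptprc, Lat, Mknk2, Tpi1, Arrb2, Rrm2, Gramd1a and Flna may come from reads of spliced transcripts. All 9 (100%) could be read with intron ends when a shift of up to 5 bases was allowed, against 3.39% of other long deletions (two-sided Fisher's exact test, p = 1.12e-09, and 6.90e-09 with the Lat deletions counted once), and without a shift 3 of the 8 genes against 1 of 59 (p = 0.00440). The reading with a shift argues against genomic deletions at arbitrary positions, but the flanking bases that a shift needs were not checked. With a shift the lower end of the interval was 66.4% (63.1% with Lat counted once) and the upper end for other long deletions 11.7%. Without a shift the lower end was 13.7% over the 9 and 8.52% with Lat counted once, against an upper end of 9.09%. Only the first of these lay above it. The 9 were picked as exonic or at splice sites, while the others were intronic or intergenic. Part of this contrast may therefore come from the selection. A processed copy in the reference genome predicted a mapping quality under 60 in most of the 9. Full mapping quality was found in 100% of them, but also in 46 of the 59 other long deletions. This test cannot decide, because reads placed on such a copy would not be called at the gene. Short inserts of another library cannot be told either. The median insert was shorter than the 256 bases of other long deletions over the 9 (difference -121, exact permutation test, two-sided, p = 0.00929). With Lat counted once this was not clear (difference -66, exact permutation test, two-sided, p = 0.0978). Reads from another library and a processed copy, whether in the reference or present only in the cells, remain open. The splice-site insertions in Vim, Serinc3, Lgals1 and Hprt were not part of these tests.

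Calls within 1 kb of another may arise from reads shared between similar sequences, as in Skint5, Vmn2r89 and Klra15. Of clustered single-base calls, 83.6% had an alternative mapping quality under 60, against 59.6% of isolated ones (two-sided Fisher's exact test, p = 3.99e-63, with calls in clusters not independent). The mixed background (C57/BL6*DBA2 per the labels) could bring a strain haplotype carried by 1 library only. As the source of most clustered calls, a haplotype in all cells of that library is argued against by the allele share. The share was 0.35 or more in 5.17% of the 1818 autosomal clustered single-base calls, with a median of 0.147. Over all autosomal calls 6.21% reached 0.35, so the low share was not particular to clusters. A haplotype in a minor part of the cells remains open.

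The T-to-G calls with full mapping quality may reflect low base quality. Their alternative bases had a median base quality of 28 against 33 in other single-base calls (difference -5, permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples give), which just met the size set beforehand. An excess confined to calls with fewer than 7 alternative reads is argued against. T-to-G made up 56.5% of calls with 7 or more alternative reads and 23.7% of calls with fewer (two-sided Fisher's exact test, p = 7.39e-15). Weak support is not excluded by this split. The 83 T-to-G calls with 7 or more reads had a median of 8 reads, against 11 in the 64 other calls. Their median share was 0.201, and 4 of them passed the 3 thresholds, against 30 of 64 other calls.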
